A study of Mus musculus with 39 samples.

How the data were processed

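Total RNA of 39 mouse tissue samples was extracted with a Qiagen RNeasy kit and biotin-labelled cRNA was prepared with the Affymetrix 3' IVT Express protocol, per the labels' protocols. The deposited table holds log2 values of 45101 probe sets, which per the submitters' processing notes were made with RMA. This method corrects background, normalizes between arrays and summarises the probes of each probe set; its version is not given in the sources used here. The values ran from 1.65 to 14.61, and 0 columns of the table were left unused. Probe intensities and detection calls were not used here, so a low log2 value was not separated from background.

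Probe sets were named from the platform annotation, checked against a RefSeq gene table of mouse assembly GRCm38.p6. Of the probe sets, 34958 carried 1 gene, 932 carried several and were not named, and 9211 had no gene in the annotation used here; 204 of the first kept the platform's symbol because their gene was not matched in that table. Each of 18194 genes was represented by its brightest probe set over all arrays, with probe sets marked as cross-hybridising used only for the 100 genes that had no other. No genome was used, so no positions are given.

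Samples were grouped by the genotype and tissue labels into 6 groups, and the number behind an array's group name orders the samples only. Animals were read from the shared identifier in the sample titles: 15 quadruple, 8 triple K5Cre, 2 triple Bcat, 2 with masses, 1 with ventral tumours and 4 with normal gland, of which T627 and T635 also gave triple K5Cre breast arrays. All arrays entered a single limma fit with a mean per group, so that the groups share an estimate of the spread. The animal was a random block (duplicateCorrelation, consensus correlation 0.329), and eBayes used an intensity trend. Because the block weighs arrays of an animal together, a fitted log2 difference need not equal the difference of the 2 printed means. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 18194 genes, separately in each of 7 comparisons: quadruple, triple K5Cre and triple Bcat each against normal gland, and quadruple against each of the other 4 groups. The 3 comparisons with normal gland share the same 4 arrays, and no overlap between their calls is claimed. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

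A set of 33 gene lists, 15 of pathways and 18 of cell types or tissues, was written down before the data were examined, with 498 of 536 members measured. Each list was tested against all other genes with limma's cameraPR, with a preset correlation between genes of 0.01 and also with a correlation estimated from the data, and adjusted over the 33 lists of a comparison. A list's adjusted p is at the preset correlation unless stated. Counts of members are given over all genes and adjusted over the list alone. The adipocyte, skeletal muscle, squamous and luminal lists also served as covariates in added fits.

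The rule for the genes named was set at the same time. It takes in each comparison the 8 largest rises and 8 largest falls among called genes, skipping clone and Riken names. It takes up to 2 rises and 2 falls per list described, or the 2 smallest p where none passed. Ctnnb1, Krt5, Krt14, Krt8, Krt18, Axin2, Lef1, Mki67, Adipoq and Epcam are given in every comparison. Single-array outliers were sought only among the lists of oncogenes and tumour suppressors. Any gene named outside this rule is said to be so.

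The alternatives fixed beforehand were no block, animal means, a fit of the compared groups alone, leaving out the third of genes with the lowest mean, and cyclic loess normalization. Others were array weights, the mean of all probe sets of a gene, eBayes without a trend, the adipocyte list mean as a covariate in the 4 comparisons between breast or tumour groups, a paired fit of the 2 animals with both tissues, and leaving out each array of groups with 2 to 5 arrays. In the fit of triple Bcat and normal gland alone, the correlation of the full fit was used, since none could be estimated from those arrays. Chosen after seeing the data were fits without the 3 arrays low in Xist and without the quadruple array lowest in Epcam, and fits with adipocyte and muscle covariates (comparisons with normal gland) or squamous and luminal covariates (the other comparisons). The whole comparison of arrays with K5Cre and Bcat arrays without it was also chosen after seeing the data. Results of a list or its members were not judged in a fit that used that list as a covariate, which left out 78 values.

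The fit was tested on simulated data for the 18194 genes with these groups and a block correlation of 0.3. Of 100 genes changed by 1 log2 unit it called 72 in quadruple against normal gland, 72 in triple K5Cre against normal gland, 59 in triple Bcat against normal gland, 80 in quadruple against triple K5Cre, 58 against triple Bcat, 54 against the masses and 49 against the ventral tumours, with 5 to 12 unchanged genes called in each. Single values were compared by exact permutation where a group had under 10 values, or with 100000 resamples otherwise, as in the one-sided test of whether arrays of an animal are alike. Tests were two-sided unless stated, and bootstrap intervals used 10000 resamples. Other splits into groups of the same sizes were fitted for each comparison with at least 3 arrays per group, up to 100 splits each, first of the arrays and then of whole animals. The tests made on these splits were chosen after seeing the data. The splits of triple K5Cre and normal gland moved the 2 tissues of T627 and T635 separately. The labels give no scan or processing batch, so none was tested. That each identifier is an animal is read from the titles, and nothing else ties arrays to animals. No 2 arrays of a quadruple animal held the same values; the closest, those of animal Q190, correlated at 0.996 over genes and were kept as 2 arrays within the animal block. The comparison of 2 animals with both tissues rests on those titles too. The Cre control probe sets of the array are spike-in controls and bear on no genotype.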

Results

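Expression was measured on 39 Affymetrix mouse arrays, 1 array per tissue sample, and the deposited log2 values of 18194 named genes were compared between 6 groups set by genotype and tissue. The genotype labels combine 4 elements written SB, Tg, K5Cre and Bcat, and the series title names Sleeping Beauty, a transposon used for insertional mutagenesis. Ctnnb1, the gene of beta-catenin, and Krt5, a keratin of basal epithelium, are therefore given first in each comparison. The quadruple group (SB/Tg/K5Cre/Bcat) had 19 breast arrays from 15 animals. The triple K5Cre group (SB/Tg/K5Cre) had 8 breast arrays from 8 animals, and the triple Bcat group (SB/Tg/Bcat) had 3 breast arrays from 2 animals. A further 2 arrays came from masses in the breast of 2 Bcat +/- animals, and 3 arrays from ventral tumours of 1 Bcat +/- animal. Normal mammary gland gave 4 arrays from 4 animals: 2 of the triple K5Cre genotype, 1 quadruple and 1 triple Bcat. The labels call the quadruple and triple samples breast and do not say that they are tumours. Array medians lay between 5.10 and 5.27 on the log2 scale, and the number of arrays limits the precision.

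**Figure D1:**
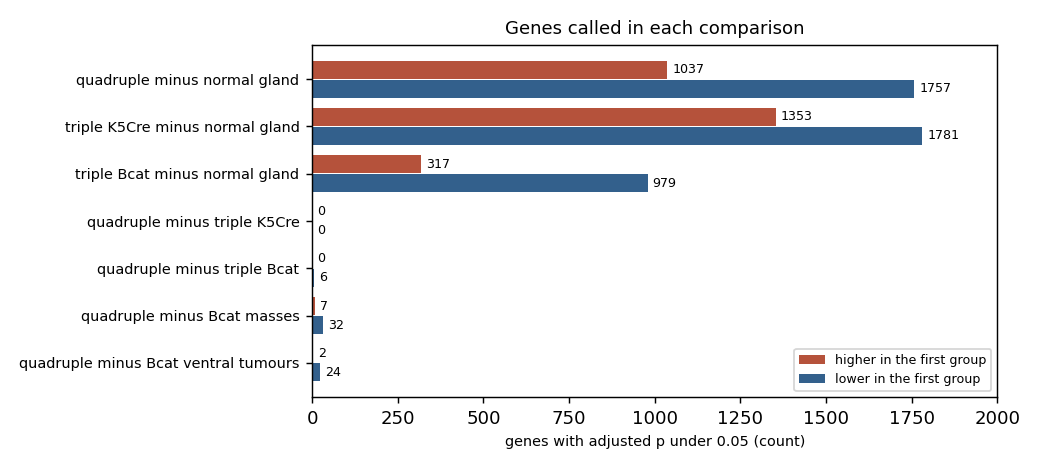
Number of genes with an adjusted p under 0.05 in each of the 7 comparisons (x axis, count of 18194 genes tested; bars split into genes higher and genes lower in the first-named group). The 3 comparisons with normal gland have 1296 to 3134 such genes, and the 4 comparisons between the other groups have 0 to 39.

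The first comparison set the quadruple breast arrays (19 arrays) against normal mammary gland (4 arrays). Ctnnb1 stood at 12.87 ± 0.24 (SD) against 12.67 ± 0.21, a fitted log2 difference of 0.18 (SE 0.13, adjusted p = 0.384), and Krt5 at 11.65 ± 1.05 against 9.80 ± 0.73 (1.55, SE 0.70, adjusted p = 0.135), so neither passed the test. Genes of cell division rose together. All 19 measured members of the mitotic list rose, with a median log2 difference of 1.78, among them Cenpe, a kinetochore motor (2.95, SE 0.44), Bub1, a spindle checkpoint kinase (2.28, SE 0.42), and Mki67, a marker of cycling cells (2.07, SE 0.33, adjusted p = 2.76e-05). The mean of this list in 18 of the 19 quadruple arrays lay above its highest value in normal gland (8.41 ± 0.63 against 6.52 ± 0.50). Of 21 DNA replication genes 16 rose, and 20 when adjusted over the list alone; Rrm2, a subunit of ribonucleotide reductase, rose by 2.40 (SE 0.40) and Tk1, thymidine kinase, by 1.68 (SE 0.34).

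Markers of fat and skeletal muscle showed the largest falls of the lists in the quadruple arrays. All 14 adipocyte genes fell (median -3.96), including the adipokine Adipoq (-6.46, SE 1.57) and the lipid droplet gene Cidec (-6.30, SE 0.99), and the list mean of all 19 arrays was below that of every normal gland. All 15 skeletal muscle genes fell (median -5.64), including Tnnc2, fast troponin C (-7.15, SE 1.62), and the myosin heavy chain genes Myh4 (-6.93, SE 1.502) and Myh1 (-6.36, SE 1.52), with 17 of 19 arrays below every normal gland. The other large falls were Amy1, an amylase (-6.87, SE 0.98), the retinol carrier Rbp4 (-6.72, SE 1.01), the troponin Tnnt3 (-6.60, SE 1.43) and Pck1, an enzyme of gluconeogenesis and glyceroneogenesis (-6.41, SE 1.07). In the endothelial list 8 of 12 genes fell (10 when adjusted over the list alone), such as the angiopoietin receptor gene Tek (-2.03, SE 0.45). In the fibroblast list 5 of 12 fell, such as Dpt (-4.05, SE 1.01). With a preset correlation between genes, the list tests gave adjusted p = 2.46e-21 for mitosis, 2.11e-13 for replication, 4.68e-17 for adipocytes, 5.94e-14 for muscle, 0.000169 for endothelium and 0.00795 for fibroblasts. With an estimated correlation none of these passed: adjusted p = 0.154, 0.327, 0.0523, 0.270, 0.506 and 0.627 in the same order. A fit with the adipocyte and muscle list means as covariates, chosen after seeing the data, turned some of these falls. The endothelial list passed in the upward direction there (median 0.31, adjusted p = 0.0105 with the preset correlation and 0.774 with an estimated one), with Tek at 0.27. The fibroblast list lost its call and turned upward (median 0.64, adjusted p = 0.0576), with Dpt at 1.31, and Pck1 stood at 0.25. No breast array reached the adipocyte mean of a gland, so the differences from normal gland in that fit are extrapolated. The nearest, quadruple 2, was at 11.66 against 11.72 in the lowest gland. Lists not described for this comparison moved up in it too, such as B cell (median 1.27, adjusted p = 1.42e-08) and matrix (0.83, adjusted p = 0.000327). With an estimated correlation these had adjusted p = 0.0977 and 0.774.

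Genes of stratified and squamous epithelium were among the largest rises in the quadruple arrays. The 8 largest were Serpinb11 (4.23, SE 1.39), Them5 (4.23, SE 1.39), the desmosomal cadherin gene Dsc3 (4.20, SE 1.20), the keratin gene Krt79 (3.95, SE 1.30), the carbonic anhydrase gene Car12 (3.69, SE 0.59), the epidermal protease gene Asprv1 (3.67, SE 1.28), Dmkn (3.604, SE 1.23) and the epidermal transcription factor gene Grhl3 (3.34, SE 1.06). All 23 genes of the squamous list had a higher mean than in normal gland (median 3.39), but only Dmkn passed the test, and none when adjusted over the list alone, since the list mean varied widely between arrays (8.65 ± 2.48 against 5.54 ± 1.45). The list test gave adjusted p = 3.38e-05, and 0.601 with an estimated correlation. Of 19 epithelial junction genes 6 rose (7 over the list alone, median 0.68, list adjusted p = 0.0163, and 0.506 with an estimated correlation). Of 13 ERK feedback genes 3 rose, led by the ETS factor gene Etv4 (1.81, SE 0.49) and the phosphatase gene Dusp5 (1.26, SE 0.33), with list adjusted p = 0.0179, and 0.506 with an estimated correlation. Of 11 p53 targets 3 rose, with Perp (2.06, SE 0.62) and the cell cycle inhibitor gene Cdkn1a (1.86, SE 0.50) the largest (list adjusted p = 0.00307, and 0.506 with an estimated correlation). With the adipocyte and muscle covariates none of these lists kept its call. The squamous median was then 0.55 (adjusted p = 0.0612) and the junction median 0.21 (adjusted p = 0.131). The ERK feedback and p53 medians turned to -0.14 (adjusted p = 0.887) and -0.11 (adjusted p = 0.931), with Etv4 at -0.13 and Cdkn1a at -0.17.

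Among 23 canonical Wnt targets only Cd44 rose (1.13, SE 0.37), and the list did not pass (median 0.54, adjusted p = 0.0975). The differences of Axin2 (0.32, SE 0.67, adjusted p = 0.821) and Lef1 (0.48, SE 0.53, adjusted p = 0.620) were within their errors. In 36 oncogenes hit by insertional mutagens, 2 rose and 5 fell, the largest being the growth factor gene Fgf10 (-2.26, SE 0.30) and the receptor genes Notch1 (0.92, SE 0.26) and Pdgfra (-1.61, SE 0.53). The list did not pass (list adjusted p = 0.963), and 2794 of all 18194 genes were called in this comparison. Of 32 tumour suppressors 3 rose and 0 fell, led by Cdkn2a (2.31, SE 0.68) and the DNA repair gene Brca1 (1.56, SE 0.36), and the list did not pass (list adjusted p = 0.0975). The estrogen receptor gene Esr1, a luminal marker, fell by 3.00 (SE 0.81), and it alone of 15 luminal genes passed. The luminal keratin genes Krt8 (-0.72, SE 0.56) and Krt18 (-0.76, SE 0.58), the epithelial adhesion gene Epcam (-0.26, SE 0.52) and the basal keratin gene Krt14 (2.17, SE 0.91) did not pass, with adjusted p from 0.107 to 0.811. None of 10 milk protein genes passed (median -1.58, list adjusted p = 0.332). With the adipocyte and muscle covariates the milk protein list passed in the upward direction (median 2.68, adjusted p = 0.00816 with the preset correlation and 0.774 with an estimated one), and Pdgfra stood at 0.20.

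In limma's test with Benjamini-Hochberg adjustment, 2794 genes differed between quadruple breast and normal gland, 1037 higher and 1757 lower, of which 288 and 920 differed by at least 2-fold. The count was 1671 without normal gland 3, 1741 without the 3 arrays low in Xist, 6749 with array weights, and 50 (2 higher, 48 lower) with the adipocyte and muscle list means as covariates. In that last fit the median difference of the mitotic list was 0.72 (list adjusted p = 4.35e-08, and 0.754 with an estimated correlation), against 1.78 without the covariates. That of the replication list was 0.25 (list adjusted p = 0.0263, and 0.817 with an estimated correlation), against 1.06, and the median SE of the 2794 genes was 0.297, against 0.215.

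**Figure D2:**
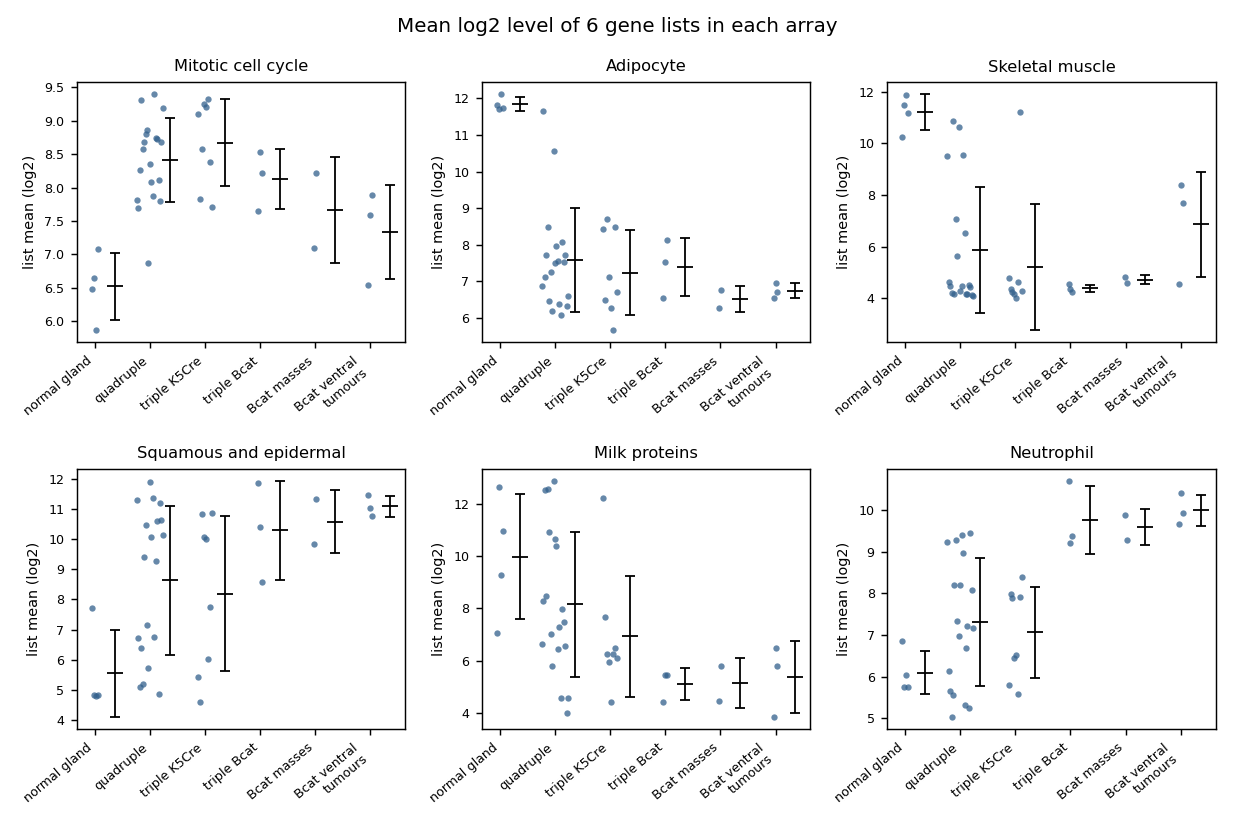
Mean log2 level of 6 gene lists (y axis) in each of the 39 arrays, by group (x axis); each point is an array, and the bar beside it is the group mean with its SD. Adipocyte means lie near 11.9 in normal gland and at 7.58 ± 1.43 in the quadruple group, and neutrophil means are at 9.59 to 10.002 in the 3 Bcat groups without K5Cre.

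The triple K5Cre breast arrays (8 arrays) differed from the same 4 normal glands in 3134 genes, 1353 higher and 1781 lower (385 and 991 by at least 2-fold). Ctnnb1 did not pass (12.96 ± 0.23 against 12.67 ± 0.21, difference 0.26, SE 0.13, adjusted p = 0.191), nor did Krt5 (10.65 ± 2.14 against 9.80 ± 0.73, difference 0.55, SE 0.72, adjusted p = 0.673). All 19 mitotic genes rose (median 2.02), with Cenpe at 3.07 (SE 0.45), Bub1 at 2.58 (SE 0.44) and Mki67 at 2.01 (SE 0.34), and all 21 replication genes rose (median 1.11), with Rrm2 at 2.34 (SE 0.42) and Tk1 at 2.13 (SE 0.35). The mitotic mean of each of the 8 arrays was above that of every normal gland. All 14 adipocyte genes fell (median -4.25), led by Thrsp, a regulator of lipogenesis (-6.79, SE 1.55), and Cidec (-6.37, SE 1.03). All 15 muscle genes fell (median -6.46), led by Tnnc2 (-8.12, SE 1.67) and Myh4 (-7.82, SE 1.55), with Myh1, Tnnt3, Acta1 and Ckm between -7.55 and -6.82. Cyp2e1, a cytochrome P450 gene, fell by 6.69 (SE 0.94), and Adipoq by 6.27 (SE 1.62). Krt14 (1.19, SE 0.94), Krt8 (-0.63, SE 0.58), Krt18 (-0.61, SE 0.60), Axin2 (-0.35, SE 0.70), Lef1 (0.12, SE 0.55) and Epcam (0.33, SE 0.54) did not pass.

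The 8 largest rises in the triple K5Cre arrays were Ereg, a ligand of the EGF receptor (4.21, SE 1.25), Dynap (4.09, SE 1.36), Krt79 (3.89, SE 1.34), Dapl1 (3.65, SE 1.28), Car12 (3.55, SE 0.61), Psapl1 (3.41, SE 1.19), the endothelial gene Esm1 (3.39, SE 0.57) and the potassium channel gene Kcne3 (3.35, SE 0.67). Of 13 ERK feedback genes 5 rose (6 over the list alone), led by Etv4 (1.82, SE 0.51) and Etv5 (1.81, SE 0.54). Of 32 tumour suppressors 5 rose, led by Cdkn2a (3.16, SE 0.71) and its neighbour Cdkn2b (2.08, SE 0.58), and 4 of 15 hypoxia and glycolysis genes rose, led by the carbonic anhydrase gene Car9 (2.35, SE 0.76). Neither list passed (list adjusted p = 0.216 and 0.242). In the fibroblast list 6 of 12 genes fell, led by Dpt (-4.73, SE 1.05). The Wnt pathway agonist gene Rspo1 (-3.86, SE 1.02) and Wnt2 (-2.33, SE 0.82) were the largest of 3 falls among 29 Wnt ligands, receptors and inhibitors, a list that did not pass (list adjusted p = 0.730). All 23 squamous genes had a higher mean (median 3.08), and none passed the test. Milk protein genes were lower on average (median -2.50), with Glycam1 at -5.51 (SE 1.98, adjusted p = 0.0504), and the list did not pass (adjusted p = 0.0592). In the endothelial list 2 of 12 genes fell (8 over the list alone, median -0.82): Tek (-2.41, SE 0.47) and the transcription factor gene Erg (-1.005, SE 0.30). Of 7 sebaceous gland genes 2 fell (median -0.23), Fasn (-3.40, SE 0.52) and Scd1 (-2.47, SE 0.57), which make fatty acids. Of 11 p53 targets 3 rose (7 over the list alone, median 0.61), led by Cdkn1a (2.26, SE 0.51) and Sesn2 (0.96, SE 0.29). Of 19 junction genes 3 rose (7 over the list alone, median 0.87), led by the desmosomal genes Dsc2 (2.16, SE 0.73) and Jup (1.16, SE 0.38). The list tests with a preset correlation gave adjusted p = 1.30e-22 for mitosis, 4.88e-15 for replication, 2.13e-18 for adipocytes, 4.15e-15 for muscle, 0.000669 for ERK feedback, 0.00371 for fibroblasts and 0.00119 for the squamous list. With an estimated correlation the adipocyte list kept its call (adjusted p = 0.0339), and the others did not (adjusted p = 0.123, 0.202, 0.202, 0.202, 0.694 and 0.750). The endothelial, sebaceous, p53 and junction lists had adjusted p = 0.00137, 0.0402, 0.00368 and 0.00723, and 0.661, 0.433, 0.492 and 0.492 with an estimated correlation. With the adipocyte and muscle covariates, the median was 0.91 for mitosis (list adjusted p = 9.45e-10) and 0.38 for replication (0.00513), with adjusted p = 0.768 and 0.827 with an estimated correlation. The ERK feedback list (median 0.27, adjusted p = 0.414) and the squamous list (0.38, adjusted p = 0.360) lost their calls in that fit. The fibroblast list lost its call and turned upward (0.79, adjusted p = 0.0694), with Dpt at 1.08, Rspo1 at 0.28 and Etv4 at -0.29. The endothelial list passed in the upward direction (0.52, adjusted p = 0.000128, and 0.768 with an estimated correlation), with Tek at 0.097 and Erg at 0.21. The p53 list (-0.046, adjusted p = 0.802, Sesn2 at -0.046) and the sebaceous list (0.25, adjusted p = 0.405, Scd1 at 0.093) turned, and the junction list (0.44, adjusted p = 0.0920, Dsc2 at -1.45 and Jup at -0.21) lost its call. The milk protein median turned to 1.77 (adjusted p = 0.0960).

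Breast and normal gland of 2 animals, T627 and T635, were both on arrays, and a fit of these 4 arrays with the animal as a fixed block called 0 genes in limma, a design of 2 pairs. The medians of the mitotic, adipocyte and muscle lists kept their direction, at 1.65, -4.39 and -7.49. That of the Wnt ligand, receptor and inhibitor list, which passed in neither fit, went from -0.029 to 0.0020. Breast lay above gland in the mitotic mean of both animals (7.83 against 5.87 in T627 and 8.58 against 7.07 in T635). Of 15 list results given for this comparison, 13 kept their side of the threshold in the paired fit. The milk protein (median -2.22, adjusted p = 0.000378) and tumour suppressor lists (0.093, adjusted p = 0.00768) passed in it, with the preset correlation. The count for triple K5Cre against normal gland was 1770 without normal gland 3, 1856 without the arrays low in Xist, 6283 with array weights and 22 with the adipocyte and muscle covariates.

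The triple Bcat breast arrays (3 arrays, 2 animals) differed from normal gland in 1296 genes, 317 higher and 979 lower (204 and 709 by at least 2-fold). Ctnnb1 (12.90 ± 0.43 against 12.67 ± 0.21, difference 0.15, SE 0.19, adjusted p = 0.697) and Krt5 (11.95 ± 0.35 against 9.80 ± 0.73, difference 1.89, SE 1.02, adjusted p = 0.278) did not pass. The 8 largest rises included 3 chemokine genes. Cxcl3 rose by 7.70 (SE 1.94, 10.82 ± 0.35 against 3.28 ± 0.92), Cxcl5 by 6.91 (SE 1.91), Uox, urate oxidase, by 6.37 (SE 1.74) and Cxcl2 by 6.28 (SE 1.61). The others were the stefin gene Stfa2l1 (6.15, SE 1.91), the collagenase gene Mmp13 (5.65, SE 1.81), the prostaglandin synthase gene Ptgs2 (5.28, SE 1.46) and the defensin gene Defb3 (5.20, SE 1.54). Of 8 neutrophil genes 5 rose, and all 8 when adjusted over the list alone (median 3.62), with the cytokine gene Il1b at 4.67 (SE 1.14) and the neutrophil collagenase gene Mmp8 at 3.82 (SE 0.79). All 15 muscle genes fell (median -7.19, Tnnc2 -9.12, SE 2.37, with Myh4, Myh1, Tnnt3, Ckm and Tnni2 between -8.55 and -7.46). Amy1 fell by 7.61 (SE 1.44), and 11 of 14 adipocyte genes fell (13 over the list alone, median -3.77), with Thrsp at -7.65 (SE 2.18) and Adipoq at -7.24 (SE 2.29). Krt14 (3.25, SE 1.33), Krt8 (-1.15, SE 0.82), Krt18 (-1.43, SE 0.85), Axin2 (0.91, SE 0.98), Lef1 (0.71, SE 0.78) and Epcam (-1.01, SE 0.76) did not pass.

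Of the 19 mitotic genes 6 rose in triple Bcat arrays, and 18 when adjusted over the list alone (median 1.48), with Bub1 at 2.05 (SE 0.61) and Mki67 at 1.66 (SE 0.48). All 23 squamous genes had a higher mean (median 5.27); none passed over all genes and 17 did over the list alone, with Krt6a, a keratin of wound and hyperproliferative epidermis, at 5.83 (SE 1.91, adjusted p = 0.0560). All 10 milk protein genes had a lower mean (median -5.13), 0 passed over all genes and 4 over the list alone, with the casein gene Csn2 at -7.64 (SE 2.54, adjusted p = 0.0599). Col12a1, a fibril-associated collagen gene, rose by 3.77 (SE 1.08), 1 of 17 matrix genes (3 over the list alone, median 0.97). Of 21 replication genes 2 rose (median 0.72), Rrm2 (1.91, SE 0.59) and Rrm1 (1.16, SE 0.32), and 3 of 7 sebaceous gland genes fell (median -0.71), among them Fasn (-3.36, SE 0.74) and Scd1 (-2.84, SE 0.81). None of 19 junction genes (median 0.46) or 23 hair follicle genes (median 0.79) passed, with Dsc3 at 5.43 (SE 1.76), Pkp3 at 1.85 (SE 0.60), Padi3 at 3.62 (SE 1.25) and Tchh at 4.80 (SE 1.91). The gland of the triple Bcat genotype, normal gland 1, had a hair follicle mean of 8.02, above every triple Bcat breast array (6.47 to 7.54). Its Axin2 (9.07) was also above the triple Bcat mean (8.58 ± 0.74). Its squamous mean (7.71) was below every triple Bcat array (8.59 to 11.9). The list tests gave adjusted p = 1.05e-08 for neutrophils, 1.01e-10 for mitosis, 1.43e-09 for the squamous list, 0.00386 for milk proteins, 2.14e-14 for muscle and 5.20e-13 for adipocytes with a preset correlation, and 0.126, 0.467, 0.467, 0.683, 0.221 and 0.126 with an estimated correlation. For replication, sebaceous gland, matrix, junctions and hair follicle they gave 3.01e-05, 0.0264, 0.0173, 0.0202 and 0.0405, and 0.683, 0.467, 0.683, 0.683 and 0.683 with an estimated correlation. With the adipocyte and muscle covariates the mitotic median was 0.30 (adjusted p = 0.1004) and the milk protein median -0.23 (adjusted p = 0.898), so both lists lost their calls. The squamous median was 2.40 (adjusted p = 0.000437) and the neutrophil median 3.82 (adjusted p = 6.18e-09) in that fit, with adjusted p = 0.878 and 0.107 with an estimated correlation. The replication median turned to -0.23 (adjusted p = 0.657), with Rrm2 at -0.0019. The sebaceous (-0.21, adjusted p = 0.767), junction (0.23, adjusted p = 0.294) and hair follicle (0.091, adjusted p = 0.630) lists lost their calls, and the matrix median was 2.03 (adjusted p = 1.44e-08, and 0.476 with an estimated correlation). The count was 381 without triple Bcat 1 and 687 without normal gland 3, 743 without the arrays low in Xist, 2033 in a fit of the 2 groups alone, 6581 with array weights and 1 with the adipocyte and muscle covariates.

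The comparison of quadruple with triple K5Cre breast arrays sets genotypes that differ in the Bcat element side by side, and no gene passed (19 against 8 arrays). Ctnnb1 was 12.87 ± 0.24 against 12.96 ± 0.23 (difference -0.08, SE 0.10, adjusted p = 0.995), and Krt5 11.65 ± 1.05 against 10.65 ± 2.14 (1.00, SE 0.55, adjusted p = 0.995). The Wnt ligand gene Wnt7b had the smallest adjusted p of the Wnt ligand list, 0.539 (7.16 ± 0.31 against 7.98 ± 0.72, difference -0.82, SE 0.18), and was the only list member to pass when adjusted over its list alone. Axin2 (0.67, SE 0.53) and Lef1 (0.36, SE 0.42), both direct Wnt targets, differed by less than the spread between arrays, as did Mki67 (0.06, SE 0.26). So did Krt14 (0.98, SE 0.71), Krt8 (-0.10, SE 0.44), Krt18 (-0.14, SE 0.45), Adipoq (-0.19, SE 1.23) and Epcam (-0.59, SE 0.41). Milk protein genes were higher on average in the quadruple arrays (median 1.32, Csn2 2.37, SE 1.36), as were T cell genes (median 0.40), and ERK feedback genes were lower (median -0.30, Spry1 -0.59, SE 0.22). These lists passed with a preset correlation (adjusted p = 0.0124, 0.00916 and 0.00572), and with an estimated correlation each had adjusted p = 0.905. The T cell list mean was highest in quadruple 2 (7.70) and quadruple 8 (6.996), with quadruple 1 next (6.22), against 4.43 to 5.49 in the triple K5Cre arrays.

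limma called 0 genes between quadruple and triple K5Cre arrays, with 811 genes at an unadjusted p under 0.05. The count was also 0 with no block, with animal means, in a fit of the 2 groups alone, without the third of genes with the lowest means, with cyclic loess and with array weights. It was 0 too with the mean of probe sets, without a trend and with the adipocyte or the squamous and luminal covariates. It was 1 without the arrays low in Xist (Ttc36, -1.83, adjusted p = 0.0391, a gene chosen after its value was seen). In simulated data with these groups, 80 of 100 genes changed by 1 log2 unit were called.

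The quadruple arrays were next set against the other genotypes without K5Cre. Against triple Bcat (3 arrays), 6 genes were lower and 0 higher: the secreted protein gene Prok2 (-1.89, SE 0.34, adjusted p = 0.0132), the meiotic gene Sycp2 (-1.07, SE 0.15), Bpifb9b (-1.03, SE 0.16), Lgi3 (-0.89, SE 0.17) and 2 genes known by clone or accession names. Ctnnb1 (0.03, SE 0.16) and Krt5 (-0.33, SE 0.86) did not differ beyond their errors. Krt14 (-1.09, SE 1.13), Krt8 (0.43, SE 0.69), Krt18 (0.67, SE 0.72), Axin2 (-0.59, SE 0.83), Lef1 (-0.23, SE 0.66), Mki67 (0.41, SE 0.41), Adipoq (0.79, SE 1.94) and Epcam (0.75, SE 0.64) did not pass either. None of 8 neutrophil genes passed over all genes and 6 were lower over the list alone (median -2.60), with Mmp8 at -3.23 (SE 0.67, adjusted p = 0.0536); the list test gave adjusted p = 4.65e-11, and 0.0576 with an estimated correlation. Its mean was below that of every triple Bcat array in 15 of 19 quadruple arrays. Milk protein genes were higher in the quadruple group (median 3.16, Csn2 6.06, SE 2.15, adjusted p = 0.583) and squamous genes lower (median -1.92), with list adjusted p = 0.000754 and 0.000128, and 0.551 and 0.574 with an estimated correlation. The count was 10, 15 and 11 without triple Bcat 1, 2 and 3, 14 with no block, 2557 with array weights and 0 once the third of genes with the lowest means was left out, which held all 6. The 4 genes named had means of 5.41 or lower in both groups.

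Against the Bcat +/- masses (2 arrays), 39 genes differed, 7 higher and 32 lower in the quadruple group. The identifiers of the mass animals begin with C57 and those of the quadruple animals do not, so the difference cannot be told apart from the identifier series. Ctnnb1 (0.08, SE 0.18) and Krt5 (-1.01, SE 0.95) did not pass, nor did Krt14 (-1.55, SE 1.25), Krt8 (-0.22, SE 0.76), Krt18 (0.26, SE 0.79), Axin2 (0.22, SE 0.92) and Lef1 (0.23, SE 0.73). Mki67 (0.96, SE 0.45), Adipoq (2.31, SE 2.14) and Epcam (0.13, SE 0.71) had adjusted p from 0.585 to 0.979. The homeobox genes Hoxb6 (4.29 ± 1.35 against 7.74 ± 1.20, difference -3.45, SE 0.74) and Hoxb9 (-3.44, SE 0.74), which mark position along the body axis, were lower. So were the growth factor binding gene Fgfbp3 (-3.86, SE 0.62), Ugt2b34 (-3.74, SE 0.82), the aldo-keto reductase gene Akr1c19 (-3.55, SE 0.37), Mmp8 (-3.52, SE 0.74), Serpina7 (-3.28, SE 0.57) and Hgfac (-3.01, SE 0.60). The 2 masses were far apart for Ugt2b34 (9.80 in mass 1 and 3.42 in mass 2, against 2.85 ± 0.63 in the quadruple arrays) and Serpina7 (8.69 and 2.45, against 2.29 ± 0.12). Without mass 1 their differences were -0.55 and -0.16, with Akr1c19 at -2.12, Hoxb9 at -2.29 and Hgfac at -1.77; without mass 2 those of Ugt2b34 and Serpina7 were -6.93 and -6.398. Of the 15 named genes that passed, Akr1c19 and ND5 kept the call without mass 1, and 9 kept it without mass 2. The 7 higher genes were Wdfy1 (1.81, SE 0.32), the RNA processing genes Pcf11 (1.65, SE 0.32) and Scaf11 (1.20, SE 0.25), Plekha5 (1.54, SE 0.31), Dnajb12 (1.23, SE 0.27), the mitochondrial gene ND5 (1.10, SE 0.19) and the cohesin loader gene Mau2 (0.94, SE 0.16). Mmp8 was 1 of 8 neutrophil genes to fall (3 over the list alone, median -2.19, list adjusted p = 6.97e-07, and 0.439 with an estimated correlation). With 2 arrays the count moved from 5 without mass 1 to 89 without mass 2, and it was 21 in a fit of the 2 groups alone, 10 without the third of genes with the lowest means and 498 with array weights.

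Against the ventral tumours of the Bcat +/- animal (3 arrays), 26 genes differed, 2 higher and 24 lower. Ctnnb1 (0.11, SE 0.18) and Krt5 (-0.58, SE 0.999) did not pass, nor did Krt14 (-1.42, SE 1.31), Krt8 (0.67, SE 0.80), Krt18 (0.71, SE 0.83), Axin2 (0.14, SE 0.96) and Lef1 (0.28, SE 0.76). Mki67 (1.27, SE 0.47), Adipoq (1.78, SE 2.24) and Epcam (1.11, SE 0.74) had adjusted p from 0.435 to 0.842. The lower genes included the lubricin gene Prg4 (4.67 ± 0.91 against 9.63 ± 0.37, difference -4.98, SE 0.90), the fibroblast gene Pi16 (-4.68, SE 0.80), the neutrophil granule gene Ngp (-4.67, SE 0.84), Ifitm6 (-4.32, SE 0.87), Reg1 (-4.31, SE 0.47), Mmp8 (-3.93, SE 0.78), Hoxb6 (-3.62, SE 0.77) and Hoxb9 (-3.52, SE 0.78). Wdfy1 (1.63, SE 0.33) and the RNA-binding gene Rbm45 (0.72, SE 0.16) were higher. Ngp and Mmp8 were the 2 of 8 neutrophil genes to fall (4 over the list alone, median -2.47), and Pi16 the 1 of 12 fibroblast genes (median -1.73). Matrix genes had lower means throughout (17 of 17, median -1.63) and mitotic genes higher means (19 of 19, median 1.07), with no member past the test. The list tests gave adjusted p = 3.18e-10 for neutrophils, 7.25e-10 for fibroblasts, 1.40e-09 for matrix and 3.18e-10 for mitosis, and 0.0996, 0.276, 0.282 and 0.331 with an estimated correlation. Of the 10 named genes that passed, Prg4, Pi16, Ngp and Reg1 kept the call whichever tumour was left out, and each of the others lost it without at least 1 tumour (adjusted p from 0.0616 to 0.210). All 3 tumours carry 1 animal identifier, so the difference cannot be told apart from that animal. The count was 7 with animal means, 255 with no block, 45 without tumour 1, 10 without the third of genes with the lowest means, 58 with the adipocyte covariate and 3759 with array weights.

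Arrays of the same quadruple animal were on average more alike than arrays of different animals, with a call that was lost in 1 alternative. Over genes, the mean correlation of deviations from the group mean was 0.228 for the 5 same-animal pairs and -0.0577 for the 166 other pairs (difference 0.286, one-sided permutation p = 0.0398, and 0.0517 without the third of genes with the lowest means). The pairs differed: 0.937 for animal Q190 and 0.774 for animal Q2154. The 3 pairs of animal Q648 were at -0.0602, -0.171 and -0.340, below the mean of the other pairs.

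Xist, the RNA that coats the inactive X chromosome, which was looked at outside the rule for named genes, was far lower in 3 arrays than in the rest. It stood at 5.72 in quadruple 5, 6.999 in triple K5Cre 2 and 5.64 in normal gland 3, against 10.8 to 12.9 in the other 36 arrays. The last pair came from animal T627.

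**Figure D3:**
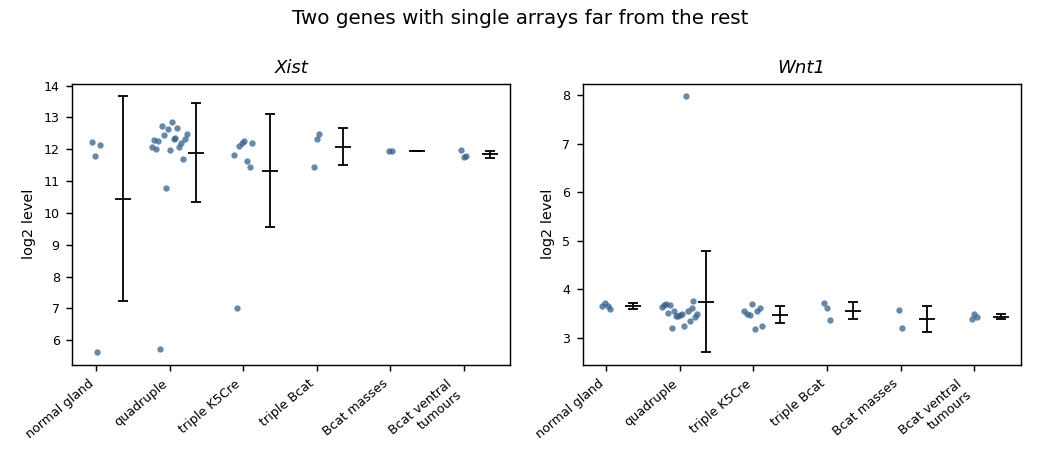
Log2 level of Xist (left) and Wnt1 (right) in each of the 39 arrays by group (x axis), with the group mean and SD beside the points. Xist is 5.64 to 6.999 in 3 arrays and at least 10.8 in the others, and Wnt1 is 7.98 in a single quadruple array and at most 3.76 in the remaining arrays with K5Cre.

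RNA quality controls showed no difference that passed correction. The 3-prime minus 5-prime signal of the Gapdh control was 0.435 ± 0.272 (SD) in the quadruple arrays, 0.230 ± 0.115 in triple K5Cre and 0.284 ± 0.0464 in normal gland. The exact permutation p was 0.0484 for quadruple against triple K5Cre (adjusted p = 0.400 over 14 tests) and 0.282 for quadruple against normal gland. Triple K5Cre differed from normal gland by -0.0542 (exact permutation p = 0.408). The beta-actin control differed by 0.0654 between quadruple and normal gland (exact permutation p = 0.662). The largest differences were those of triple Bcat from normal gland, 0.269 for Gapdh (exact permutation p = 0.0571) and 0.265 for beta-actin (exact permutation p = 0.0857), each with adjusted p = 0.400.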

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

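The test of X-linked escape genes was fixed before its result was seen; the test of Y-linked genes and the test of escape genes over animals were chosen after the low Xist values had been seen.

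Dixon's test of a single array far from its group, at the 95% level, was applied to 92 sets of values in the groups of 4 and 8 arrays and marked 13, where chance alone would mark about 4.6. In animal T627, triple K5Cre 2 had Krt5 at 5.74 (next 9.98, group median 11.2), a mean of the basal and myoepithelial list of 7.33 (next 9.16) and Xist at 6.999 (next 11.4), and normal gland 3 had Xist at 5.64 (next 11.8). Triple K5Cre 5 had Lef1 at 8.32 (next 5.02) and a hair follicle list mean of 8.72 (next 6.14). Triple K5Cre 1 had a milk protein list mean of 12.2 (next 7.68). Triple K5Cre 7 had a skeletal muscle list mean of 11.2 (next 4.77, group median 4.32), near the normal gland mean of 11.2, with a brown adipocyte list mean of 6.59 (next 5.70) and an erythroid list mean of 5.10 (next 4.30). Normal gland 1, from the triple Bcat animal, had Axin2 at 9.07 (next 7.19), a squamous list mean of 7.71 (next 4.84) and a hair follicle list mean of 8.02 (next 4.85).

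Xist was low in 3 arrays of animals Q629 and T627, in both the breast and the normal gland array of T627. Male animals are argued against, since no measured Y-linked gene of 5 stood more than 0.267 above the median of the other arrays in these 3, although no array known to be male was there to show the level of such a gene. A single X chromosome may account for it. That, or silenced copies of the genes that escape X inactivation, would lower such genes: 7 of them differed on average by -0.258 from the other arrays of their groups (exact permutation p = 0.0296 over arrays, which treats the 2 arrays of T627 as separate, with 6 of the 7 genes lower) and by -0.247 over animals (exact permutation p = 0.0467, 2 of 25 animals). That fall did not reach the 0.3 set beforehand and its 95% interval, a bootstrap over the 7 genes from -0.447 to -0.0407, spans that size, so these explanations cannot be told apart from a loss of Xist alone with 2 animals. Quadruple 5, the array of Q629, had the highest Gapdh 3-prime minus 5-prime signal of all arrays (1.176). The arrays of T627 stood at 0.282 (triple K5Cre 2) and 0.273 (normal gland 3). Whether RNA quality bears on Xist or on the fall of the escape genes was not tested. Genotype was not tested as an explanation either.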

How the results depend on the processing

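The alternatives without the arrays low in Xist, without the array low in Epcam and with 2 covariates were chosen after the data were seen. Counts of genes stayed within 1.5 times the reported count except as follows, and the cause was not tested unless given. Array weights called 6749, 6283, 6581, 2557, 498 and 3759 genes in quadruple, triple K5Cre and triple Bcat against normal gland and quadruple against triple Bcat, masses and ventral tumours. Adipocyte and muscle covariates left 50, 22 and 1 (Ranbp3l) in the 3 comparisons with normal gland, with smaller differences and larger SEs; without the arrays low in Xist these were 1741, 1856 and 743, and 1 between quadruple and triple K5Cre. The pairing of animals T627 and T635 with the animal as a block called 0 genes, with only 4 arrays in the fit. Triple Bcat against normal gland alone gave 2033. Quadruple against triple Bcat gave 14 with no block and 0 without the third of genes with the lowest means, which held all 6. Against masses it gave 21 in the fit of 2 groups and 10 without those genes, which held 26 of the 39. Against ventral tumours it gave 255 with no block, 7 with animal means, 10 without those genes, which held 14 of the 26, and 58 with the adipocyte covariate. Leaving out single arrays gave 1671 to 2253 (lowest without normal gland 3), 1770 to 2655 (normal gland 3), 381 to 1279 (triple Bcat 1; 687 without normal gland 3), 10 to 15 for quadruple against triple Bcat, 5 to 89 against masses and 26 to 45 against ventral tumours. An arm left with 1 mass is assumed to vary like the other groups. Of the list tests, 82 passed with the preset correlation and 1 with an estimated one. The same-animal similarity was 0.286 without those genes, with p = 0.0517. Named results that passed in either fit changed direction only under the adipocyte and muscle covariates: in quadruple against normal gland Pck1 0.25, Etv4 -0.13, Cdkn1a -0.17, Pdgfra 0.20, Tek 0.27, Dpt 1.31 and the list medians of ERK feedback -0.14, p53 -0.11, milk proteins 2.68, endothelium 0.31 and fibroblast 0.64; in triple K5Cre Rspo1 0.28, Etv4 -0.29, Dpt 1.08, Tek 0.097, Erg 0.21, Scd1 0.093, Sesn2 -0.046, Dsc2 -1.45, Jup -0.21, fibroblast 0.79, endothelium 0.52, p53 -0.046 and sebaceous gland 0.25; in triple Bcat Rrm2 -0.0019, replication -0.23, and milk proteins -0.23 and sebaceous gland -0.21, where the list test turned up. Of these the milk protein list in quadruple arrays and the endothelial list in quadruple and triple K5Cre arrays passed in the other direction. The turns rest on extrapolation, since no breast array reached the adipocyte mean of a gland, although quadruple 2 came near the lowest (11.66 against 11.72). Values of named genes kept their side of the threshold 2656 times, lost the call 404 times and gained it 53 times, and those of lists 786, 25 and 13 times. Among those that kept their side, 54 of genes and 8 of lists, which passed in neither fit, changed sign, such as milk proteins in triple K5Cre (1.77). Over all genes and lists computed, named or not, genes that passed in either fit changed direction 32 times, all under those covariates, and lists 22 times under them and 7 times elsewhere.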

Other observations

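The tests in this part, among them every test of other splits of the samples and the comparison of arrays with and without K5Cre, were chosen after the results they bear on had been seen.

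The homeobox gene Hoxb6, picked after its values were seen, stood at 7.74 ± 1.20 in the 2 masses and 7.91 ± 0.37 in the 3 ventral tumours, against group means of 3.58 to 4.29 in the other groups, although single quadruple arrays reached 7.62. Ifi202b, an interferon-inducible gene picked after its values were seen, stood at 11.76 ± 0.26 in the masses and 10.97 ± 0.09 in the ventral tumours, against group means of 4.85 to 8.58. Wdfy1 was lower in the same 5 arrays (6.57 ± 0.06 and 6.75 ± 0.20) than in the other groups (means of 8.34 to 8.68). The animal identifiers of these 5 arrays begin with C57, and those of no other array do. These differences therefore cannot be told apart from whatever sets that identifier series apart. Within the quadruple group the epidermal keratin genes spanned most of the array's range: Krt1 ran from 3.44 to 13.7 and Krt10 from 6.398 to 14.1, and the mean of the milk protein list ran from 4.003 to 12.9.

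Neutrophil genes were lower on average in breast arrays with K5Cre than in the Bcat arrays without it. Over animals, the mean of the neutrophil list was 7.13 ± 1.45 (SD, n = 23) with K5Cre and 9.84 ± 0.587 (n = 5) in the triple Bcat, mass and ventral tumour animals, a difference of -2.71 (95% interval -3.45 to -1.99, exact permutation p = 0.0001221 over 98280 assignments). In a limma contrast of the same 27 and 8 arrays, 5 of the 8 genes were lower with K5Cre. They were Mmp8, neutrophil collagenase (-3.57, SE 0.45, adjusted p = 1.13e-05), the granule genes Ngp (-3.34, SE 0.49) and Camp (-1.62, SE 0.33), the chemokine receptor gene Cxcr2 (-1.92, SE 0.37) and the growth factor receptor gene Csf3r (-1.88, SE 0.48). The list had a median of -2.43 (adjusted p = 3.43e-12, and 0.0335 with an estimated correlation). Among the other lists that passed, fibroblast (median -1.19), matrix (-1.25), macrophage (-0.80) and squamous (-2.35) genes were lower and the mitotic (0.69) and milk protein (2.49) genes higher with a preset correlation, each with adjusted p = 0.575 with an estimated correlation. Genes picked after their values were seen include Chil3, a chitinase-like gene of myeloid cells (-4.04, SE 0.67), Akr1c19 (-2.12, SE 0.23) and Hoxb5 (-1.79, SE 0.30), all lower with K5Cre. The transcription factor genes Irx2 (1.97, SE 0.34) and Trps1 (2.30, SE 0.44), picked likewise, were higher.

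That contrast called 1108 genes (561 higher, 547 lower with K5Cre) in the fit first run, 1660 with the arrays as 2 pooled groups (1086 shared) and 1094 with animal means (902 shared). It rests on few animals: 90 genes were called without the ventral tumour animal, 193 and 661 without the first and second animal with masses, and 373 and 1896 without the triple Bcat animals Tbc-2173 and Tbc-266. Mmp8, Ngp and Cxcr2 passed without the ventral tumour animal (adjusted p = 0.000445, 0.00995 and 0.0359), and Camp and Csf3r did not (0.0635 and 0.0874). The differences of Camp and Csf3r were then -1.47 and -1.92, against -1.62 and -1.88 with that animal. Of 100 splits of the animals, 4 gave as many genes, the real grouping among them, and the highest other split gave 1549. Chance is not excluded by that share, since the comparison was picked after its values were seen. The neutrophil difference of -2.71 prompted the comparison, so its test decides nothing about carriage of K5Cre. The mass and ventral tumour animals are labelled Bcat +/- alone, without SB or Tg, and the triple K5Cre label holds no Bcat. The 5 animals without K5Cre also differ in identifier series and in squamous list means, and those with tumours in body site. Carriage of K5Cre cannot be told apart from any of these. Among the K5Cre arrays, the highest neutrophil means were in arrays with high squamous means. Quadruple 17 had a squamous mean of 11.2 and a neutrophil mean of 9.45, against 4.85 and 5.24 in quadruple 16. Other arrays went the other way, such as triple K5Cre 4 (10.075 and 6.45). Every Bcat array without K5Cre had a squamous mean of at least 8.59, so the neutrophil difference may reflect squamous content, which was not tested.

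Single arrays stood far from the other 26 K5Cre arrays for 8 of 68 measured oncogenes and tumour suppressors, by over 2 log2 units from the median and over 1 from the next array. Wnt1, a ligand that drives mammary tumours when overexpressed, was 7.98 in quadruple 13 (animal Q520) against 3.76 in the next array, and the oncogene Mycn was 10.8 in quadruple 14 (animal Q535) against 9.41. Low values were Erbb3 (7.16, next 9.66) and Cdh1 (8.91, next 10.96) in quadruple 8, Ccnd2 (7.54, next 8.76) and Rasa1 (6.65, next 8.91) in quadruple 3, Cdkn2a (4.29, next 5.75) in quadruple 9 and Setd2 (5.91, next 7.36) in triple K5Cre 6. Erbb3 and Cdh1 are epithelial genes, and quadruple 8 also had the lowest means of the epithelial junction list (8.39, quadruple mean 9.94 ± 0.505) and of the luminal list (7.34, quadruple mean 9.03 ± 0.947) among the 27 K5Cre arrays. Quadruple 9 had the lowest mitotic mean of the 27 (6.87), with adipocyte and muscle means of 10.55 and 10.64. In normal gland Cdkn2a stood at 6.04 ± 1.66. Quadruple 3 had the lowest fibroblast (6.49) and matrix (7.51) means of the 27. Whether tissue makeup sets these low values was not tested. Genes of like level would give 4.16 such members, so the hypothesis that these lists hold more outliers than other genes stays open (one-sided exact p = 0.0546). Transposon insertion sites were not analysed here.

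The mitotic list rose in quadruple arrays over normal gland, and 2 technical explanations were tested. If less fat and muscle only left more epithelium, epithelial junction genes would have risen as much, but over animals the mitotic mean rose by 1.95 and the junction mean by 0.84, a difference of 1.11 (95% interval 0.54 to 1.68, exact permutation p = 0.00258, 15 against 4 animals). Against that, with adipocyte and muscle covariates the median mitotic difference was 0.72 (list adjusted p = 4.35e-08, and 0.754 with an estimated correlation) in place of 1.78 and the median SE of called genes rose from 0.215 to 0.297, so tissue makeup may carry part of the rise. The Gapdh 3-prime minus 5-prime signal differed by 0.173 over animals (95% interval 0.0327 to 0.332, exact permutation p = 0.259), but RNA degradation, as far as this control gauges it, is argued against: the mitotic mean rose by 2.21 (95% interval 1.59 to 2.82, exact permutation p = 0.00794) in the 5 quadruple animals with a signal no higher than the highest gland, and by 1.82 (exact permutation p = 0.000999) in the other 10. Inherited genotype alone does not part these samples, since the gland of the quadruple animal Q440 had a mitotic mean of 6.65 and breast lay above gland within T627 and T635; what else sets the breast samples apart was not tested.

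That no gene passed between quadruple and triple K5Cre arrays was weighed in the same way. Too few arrays for a 2-fold change is argued against only for the 87.6% of genes whose 95% intervals excluded a 2-fold difference. For the remaining genes it stays open. In simulated data 80 of 100 genes with such a change were called. Both shares are over genes of all levels, genes near background among them, and the simulated change was a full log2 unit at any level. Neither share speaks for a given gene or pathway. A mix of squamous and luminal arrays within both groups is argued against for genes as a whole: with those lists as covariates 0 genes were called, and the SE was a median of 0.980 times that without them. That median is over all genes, and genes that follow the 2 lists were not looked at apart. Carriage of Bcat may still change expression by less than 2-fold. A larger change is not excluded for genes with wide intervals, such as Axin2 (0.67, SE 0.53), Lef1 (0.36, SE 0.42), Krt5 (1.00, SE 0.55), Krt14 (0.98, SE 0.71) and Csn2 (2.37, SE 1.36).

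Splits of whole animals into groups of the same sizes were fitted as well. Each count of splits that gave as many genes includes the real grouping. Chance could be excluded for quadruple against normal gland (1 of 100 splits gave as many as 2794, the highest other 356) and for triple K5Cre against normal gland (1 of 100 splits, 3134 against 1156). In the latter the 2 tissues of T627 and T635 moved separately, so the pairing of these animals was not kept. Chance could not be excluded for quadruple against triple Bcat (37 of 100 splits, 6 against 1003) or against the ventral tumours (5 of 16 splits, 26 against 1127). The splits are too few for a share under 0.05 in triple Bcat against normal gland (1 of 15 splits, 1296 against 49), and would be for the ventral tumours whatever the count. For quadruple against triple K5Cre the real count of 0 means that all 100 of 100 splits give as many (the highest other 11), so these splits decide nothing. Splits that called many times the real count, in quadruple against triple Bcat and against the ventral tumours, point to a structure of the samples, and what it is was not tested. Splits of single arrays, which part arrays of an animal, gave at most 361, 835 and 276 genes in the 3 comparisons with normal gland and 21, 424 and 434 in quadruple against triple K5Cre, triple Bcat and ventral tumours. The comparison with the masses, at 2 arrays, was not tested in this way.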
